A study of Mus musculus with 2 samples.

How the data were processed

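Tregs of male Pparg and Foxp3 reporter mice, 8 weeks of age, were pooled from 2 or 3 spleens per sort and encapsulated with the Chromium Single Cell 3′ v2 chemistry, per the labels' protocols. The authors deposited, for each of the 2 libraries, a matrix of raw UMI counts per gene and cell barcode, with 28692 genes, and no normalization was recorded. Counts were made with Cell Ranger 2.1.0 and the mm10 build, per the submitters' processing notes; the annotation behind the counts and the cell calling settings are not given in the sources used here. The label of the second group calls its cells low in PPARg, while the names of its deposited files carry the tag pos; the label's word is used throughout, and the conflict could not be settled here. The labels give no separate mice, so each group is 1 library. Coordinates of named genes were taken from GENCODE M21 (mm10), which held 28339 of the gene identifiers.

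Cells with over 10% mitochondrial UMIs were left out (373 PPARg-low and 269 PPARg-negative barcodes). A minimum of 500 genes per cell had been set to give way to 200 genes if it kept under 80% of a library's barcodes; it kept 66.5 and 79.3%, so 200 was used, and no barcode fell below it. The kept cells held 2901710 and 5897260 UMIs. Doublets were called with Scrublet in scanpy 1.11.5, which marked 11 (0.679%) and 8 (0.304%) of the kept cells; so undetected doublets stay possible, and the marked cells were kept in the main values. In all, 4 kept cells, all PPARg-negative, had 5 or more B cell marker UMIs. No cluster was led by genes of another cell type, so 0 clusters were left out. The libraries shared 5 barcode sequences.

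UMIs were summed per library over kept cells and expressed as CPM, the UMIs of a gene per 1e6 UMIs of its library, and the ratio of PPARg-low over PPARg-negative was given with an exact conditional binomial 95% interval. A gene at 0 UMIs in 1 library entered at a floor of 3 counts for that library, in list medians and within subsets of cells too. Members of a list were called higher or lower by size alone, at a ratio of 1.5 or more in either direction with the interval on the same side of 1. List medians used members with 30 or more UMIs over both libraries, with intervals from 1000 Poisson resamplings of the counts, and were placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. With 1 library per group there was no replicate spread, so no p-value was computed and cells were not used as replicates. Poisson counts were simulated from the pooled profile for the 9224 measured genes, with 200 changed genes. On these the ratio interval held the true ratio for 96.0% of unchanged and 95.0% of changed genes. The simulation had no variation between cells, mice or libraries, so it covers counting error only.

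For shares of cells and list UMIs per cell, each cell was thinned to 750 UMIs, which used 1381 of the PPARg-low and 2394 of the PPARg-negative cells and left out 238 and 239 shallower ones. Clusters came from log counts per 10000, 2000 variable genes without immunoglobulin, T cell receptor, ribosomal and mitochondrial genes, 20 components, 15 neighbours and the Leiden method (leidenalg 0.10.2, resolution 1.0), with no batch correction; cluster sizes were not compared. A cluster was given a name from a fixed list only when 3 or more of its 10 leading genes were on it: clusters 1 and 2 were resting Treg-like, cluster 4 was led by chemokine and egress receptor genes, cluster 8 was effector Treg-like, cluster 6 was led by interferon genes and cluster 9 by cell cycle genes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

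The groups, 24 gene lists, comparisons, filters and most alternatives were set before the data were examined. Genes were named by a fixed rule: Pparg and Foxp3; the 12 highest and 12 lowest genes by the interval bound nearest to 1 among 6371 genes with 100 or more UMIs that were not immunoglobulin, T cell receptor, ribosomal, mitochondrial, predicted, sex-linked marker or other-cell-type genes; up to 4 members of each list (6 for the resting, effector and nonlymphoid-tissue lists) by the same ranking; and the 15 genes of the share comparison. Some genes that this rule names are not reported here. Other members of the lists named in the text (Ikzf3, Rgs1, Il7r and Hspa8) and Ighm were chosen after their values were seen. Alternatives covered cell filters, doublets, scaling, the weight of cells, thinning, count minimums and cluster settings. The split at a 20% ribosomal share, ratios relative to the median of all genes, and the stricter cell filter for genes and shares were added after seeing the data. Ribosomal proteins (98 measured genes) had a median log2 ratio of -0.65 and mitochondrially encoded genes one of 0.47.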

Results

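Regulatory T cells (Tregs) are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. They were sorted from the spleens of male reporter mice in which a red fluorescent protein follows Pparg and a green fluorescent protein follows Foxp3, and their RNA was counted cell by cell with droplet-based 3′ sequencing. Pparg encodes PPARg, a nuclear receptor that controls lipid metabolism genes. Tregs with low PPARg reporter signal made up the PPARg-low library and Tregs without it the PPARg-negative library, so each group had 1 library, from a pool of 2 or 3 mice. No difference below has a replicate check, no test between groups was possible, and every interval is a 95% interval that covers counting error only.

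The PPARg-low library held 1992 barcodes and 3227201 UMIs (unique molecular identifiers, each standing for 1 captured transcript), and the PPARg-negative library held 2902 barcodes and 6114403 UMIs. After cells with over 10% mitochondrial UMIs were left out, 1619 and 2633 cells remained, with medians of 1517 and 2171 UMIs and of 834 and 946 genes per cell. The libraries also differed in the share of UMIs from ribosomal protein genes, which had 2 peaks in each, with no gap between them: bins of 2% from 16 to 22% each held 2.90 to 3.09% of PPARg-low and 1.18 to 1.86% of PPARg-negative cells. Cells with under 20% such UMIs, called ribosome-poor below, were 951 of 1619 in the PPARg-low library (58.7%, exact binomial 56.3 to 61.2%) and 614 of 2633 in the PPARg-negative library (23.3%, 21.7 to 25%). Their median depth was 978 and 853 UMIs, against 2294 and 2455 UMIs in the other, ribosome-rich cells. Ribosome-poor cells also had higher median mitochondrial shares, 6.80 and 6.92% against 2.74 and 2.29%, and higher median shares of the nuclear RNA Malat1, 8.13 and 8.07% against 3.50 and 2.46%, and whether they differ in state or in quality was not settled. Most list medians are therefore also given within both kinds of cells, with ratios of genes whose call the split ended and of some others; the split was chosen after seeing the data. Of 71 genes of the naming rule that were higher over all cells, 68 had a smaller ratio within ribosome-poor cells and 49 were still higher there by 1.5 times or more, against 66 within ribosome-rich cells. Of 25 that were lower, 17 were still so in ribosome-poor and 25 in ribosome-rich cells.

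**Figure D1:**
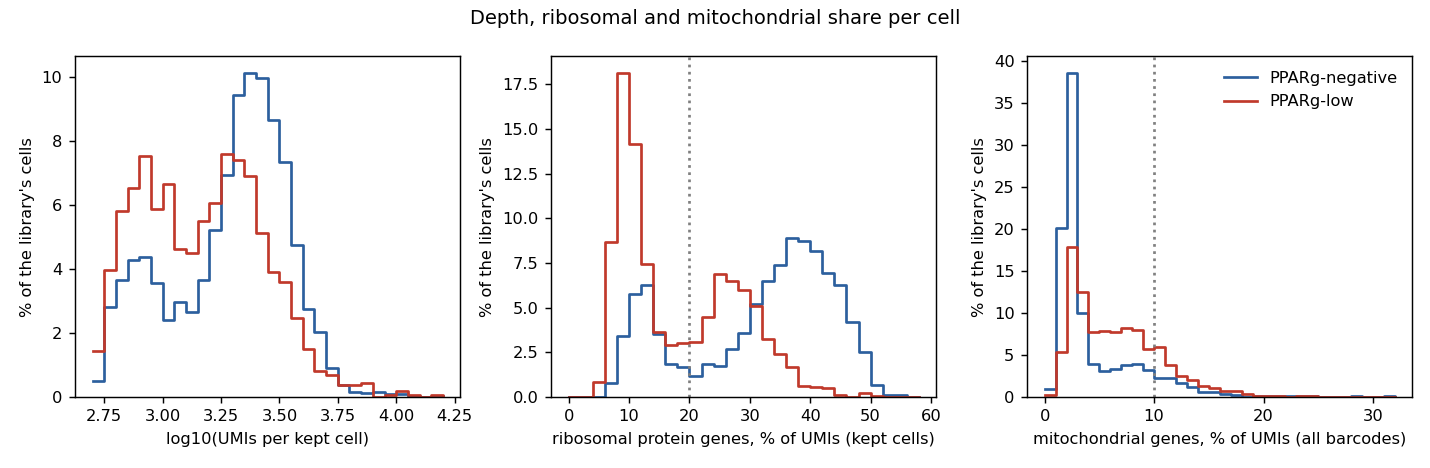
Distributions of the log10 UMI count, the ribosomal protein share and the mitochondrial share (in % of UMIs) for the PPARg-negative library (blue) and the PPARg-low library (red). The first 2 are given as % of each library's kept cells and the mitochondrial share as % of all its barcodes. Dotted lines mark the 20% ribosomal split and the 10% mitochondrial limit. The ribosomal share has 2 peaks in both libraries, which overlap around the split, with 58.7% of PPARg-low and 23.3% of PPARg-negative cells under 20%.

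The series asks whether splenic Tregs with PPARg resemble Tregs of nonlymphoid tissues, and the reporter genes came first. Pparg (ENSMUSG00000000440, mm10 chromosome 6, 115360951 to 115490399, plus strand) had 43 UMIs in the PPARg-low library, or 14.8 CPM (UMIs of the gene per 1e6 UMIs of the library), and 0 UMIs in the PPARg-negative library. Against a floor of 3 counts put in for the PPARg-negative library, Pparg was 29.1-fold higher in the PPARg-low library, and the exact counting interval of the ratio began at 22.7-fold. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand) had 100 and 146 UMIs, a ratio of 1.39 (1.07 to 1.81) for PPARg-low over PPARg-negative. Within ribosome-rich cells the Foxp3 ratio was 0.965 (0.648 to 1.41), and within ribosome-poor cells it was 1.16 (0.740 to 1.84), so no difference in Foxp3 was detectable at this depth within either. Over 9224 genes with 30 or more UMIs the median log2 ratio was 0.29, so list medians are also given relative to that value.

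Genes of activated, effector Tregs were higher in the PPARg-low library. Of 16 measured genes on that list, 15 were at least 1.5 times higher and 0 were lower, with a median of 5.18-fold (log2 2.37, 2.27 to 2.48, and 2.09 relative to all genes). The leading members were the inhibitory receptors Pdcd1 at 13.9-fold (12 to 16.3) and Lag3 at 9.63-fold (7.82 to 11.9), the transcription factor Bhlhe40 at 11.1-fold (7.42 to 17.1), and the costimulatory receptor Tnfrsf9 at 8.05-fold (7.5 to 8.66). Cd83 was 7.77-fold and Id2 6.77-fold higher, while Ikzf3 lay at 1.38-fold. The list median was 2.27 in ribosome-rich cells, with 15 members higher, and 1.43 in ribosome-poor cells, with 11 higher and 1 lower. Icos, a costimulatory receptor, was 2.94-fold higher over all cells (2.7 to 3.19) and 1.02-fold within ribosome-poor cells (0.917 to 1.14). There Pdcd1 was 6.62-fold (5.19 to 8.56), Lag3 3.54-fold (2.69 to 4.73), Tnfrsf9 4.44-fold (3.95 to 4.99) and Id2 2.54-fold higher (1.94 to 3.38).

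Genes known from Tregs of nonlymphoid tissues followed the same direction, with 15 of 17 measured members higher and 0 lower in the PPARg-low library. Their median was 4.97-fold (log2 2.31, 2.13 to 2.75, and 2.03 relative to all genes). Il10, which encodes a suppressive cytokine, was 66.8-fold higher (31.9 to 168, 230 against 7 UMIs), the chemokine receptor Ccr8 20.1-fold (12.8 to 33.2), and Klrg1, a receptor of terminally differentiated lymphocytes, 15.9-fold (14.1 to 17.9). Areg, which encodes the tissue repair factor amphiregulin, was 15.7-fold higher (7.11 to 40.8), Tnfrsf8 9.65-fold (5.58 to 17.7) and Il1rl1, the receptor for interleukin 33, 7.44-fold (5.23 to 10.8). The transcription factor genes Gata3 and Rora were 3.73-fold (3.41 to 4.07) and 2.65-fold (2.22 to 3.18) higher, and the members that passed no size threshold were Ccr2 at 1.47-fold and Rgs1 at 0.913-fold. The list median was 2.54 in ribosome-rich cells and 1.14 in ribosome-poor cells, where 13 members were higher and 1, Ccr2 at 0.435-fold (0.362 to 0.521), was lower. Klrg1 was 33.6-fold higher in ribosome-rich cells (26.9 to 42.4) and 3.71-fold in ribosome-poor cells (3.23 to 4.29). Other pooled values were larger than those within ribosome-poor cells too, where Il10 was 15.4-fold (7.34 to 38.9, 190 against 7 UMIs), Ccr8 6.96-fold (3.87 to 13.8), Areg 4.17-fold (1.77 to 12) and Il1rl1 2.07-fold higher (1.35 to 3.27). Gata3 was 2.95-fold higher there (2.46 to 3.55), and Rora lay at 1.15-fold (0.899 to 1.49).

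Genes of resting Tregs that recirculate through lymphoid organs were lower in the PPARg-low library. Of 14 measured members, 12 were lower by 1.5 times or more, 1 was higher (Il7r, 2.28-fold, and 1.45-fold in ribosome-poor cells) and the median was 3.96-fold lower (log2 -1.99, -2.15 to -1.83, and -2.27 relative to all genes). Ly6c1 was 27.9-fold lower (18.9 to 43.3), though its close paralog Ly6c2 makes that count uncertain, and Igfbp4 was 24.8-fold lower (11.3 to 68.2). The chromatin organizer gene Satb1 was 10.1-fold lower (7.71 to 13.5), and Ccr7, which guides T cells into lymph nodes, was 8.95-fold lower (6.79 to 12). Dapl1 and Bach2 were 12-fold (5.37 to 33.2) and 7.08-fold (4.04 to 13.5) lower. S1pr1, the receptor for lymphocyte exit, was 2.04-fold (1.76 to 2.36) lower. This direction was present in both kinds of cells, with a list median of -1.87 in ribosome-rich cells and -1.61 in ribosome-poor cells. In the latter Satb1 was 5.28-fold and Ccr7 13.6-fold lower, while Igfbp4 had 0 against 6 and Dapl1 0 against 3 UMIs.

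**Figure D2:**
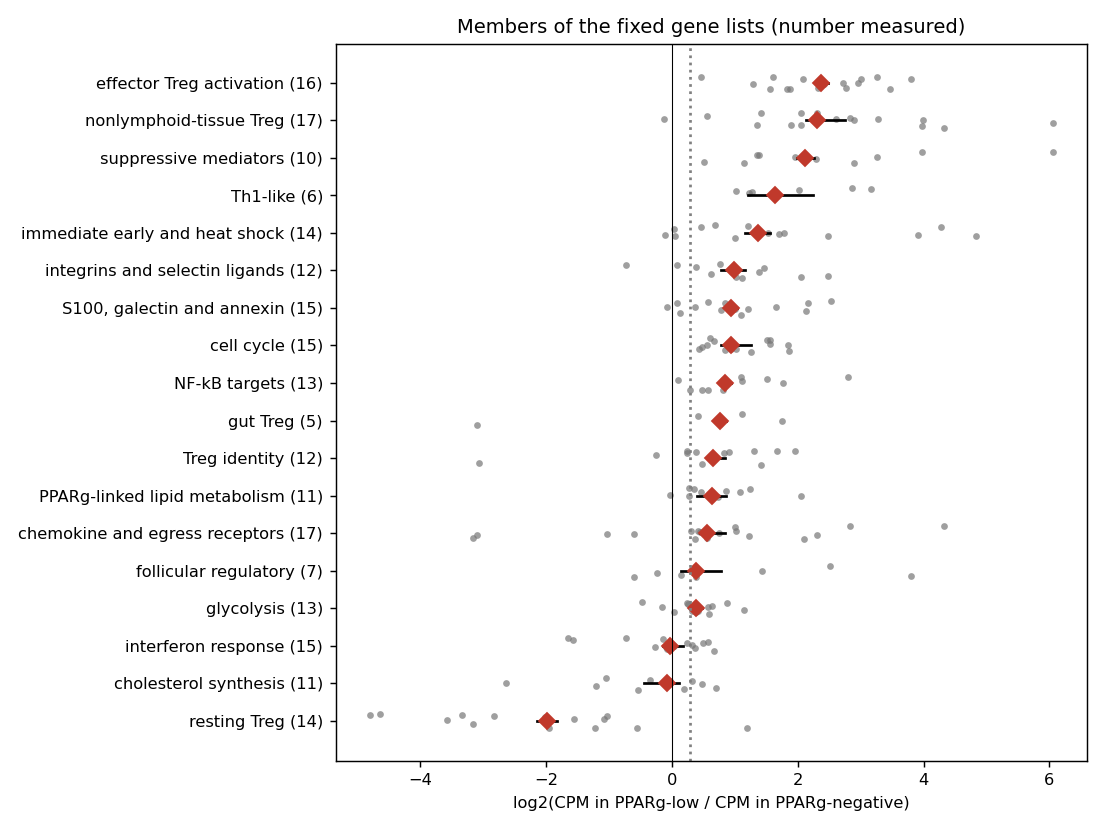
Log2 ratio of CPM in the PPARg-low over the PPARg-negative library for each measured member (grey points) of 18 gene lists, with the list median (red diamond) and its 95% counting interval (black bar); the solid line marks 0 and the dotted line the median of all measured genes, 0.29. The effector list (median 2.37) and the nonlymphoid-tissue list (2.31) lie far to the right and the resting list (-1.99) far to the left.

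Ranked over 6371 genes with 100 or more UMIs, the 12 genes highest in the PPARg-low library were Il10, Trf, Ctsh, Penk, Mt1, Klrg1, Il1r2, Ccr8, Asb2, Tshz2, Pdcd1 and F13a1. Trf, which encodes transferrin, was 54.5-fold higher (22.8 to 170, 134 against 5 UMIs), and the cathepsin gene Ctsh was 31.5-fold higher (16.7 to 67.0). Penk, the gene of the opioid precursor proenkephalin, had 1591 against 168 UMIs and was 19.2-fold higher (16.4 to 22.7). The metallothionein gene Mt1 was 26.4-fold higher (15.3 to 49.3), and Il1r2, the decoy receptor for interleukin 1, 21.3-fold (13.3 to 36.1). The 12 lowest were Ly6c1, Cnn3, Satb1, Treml2, Ccr7, Gata1, Gpr83, Nsg2, Dapl1, Ms4a4c, Tubb2a and Atp1b1. Cnn3 was 33.7-fold lower (9.15 to 281, 2 against 137 UMIs), Gata1, better known as an erythroid transcription factor gene, was 13.2-fold lower (6.56 to 30.9), and Gpr83 was 8.36-fold lower (6.47 to 11). The 12 higher and the 12 lower genes kept their direction in ribosome-rich cells. In ribosome-poor cells the interval stayed above 1 for the 12 higher and below 1 for 9 of the 12 lower genes, while Cnn3 and Dapl1 had 0 against 3 UMIs each, too few for a ratio, and Tubb2a 5 against 5 UMIs (0.568-fold, 0.131 to 2.47). The higher genes had smaller ratios in ribosome-poor cells, with Trf at 8.41-fold (3.45 to 26.7), Ctsh at 9.19-fold (4.07 to 25.7), Mt1 at 6.61-fold (3.22 to 15.8), Il1r2 at 6.08-fold (3.44 to 11.7) and Penk at 9.87-fold higher (7.35 to 13.5), while some of the lower genes differed more there, such as Gpr83 at 15-fold lower.

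Klrg1 transcripts were found in a large part of the PPARg-low cells when every cell was thinned to 750 UMIs. Its share of cells with a UMI was 41.3% of 1381 PPARg-low cells (exact binomial 38.7 to 43.9%) and 3.43% of 2394 PPARg-negative cells (2.73 to 4.23%), and 55.5 and 5.36% without thinning. Gata3 was found in 30.6 and 10.7% of thinned cells and Icos in 29.8 and 11%. Within ribosome-poor cells Icos was found in 40.6% (37.0 to 44.3%) and 37.2% (32.5 to 42.1%), with overlapping intervals, Gata3 in 35.5 and 17.4% and Klrg1 in 53.1 and 14.5%. S1pr1 was found in 6.01% of PPARg-low cells (4.82 to 7.40%) and 12.5% of PPARg-negative cells (11.2 to 13.9%), and Ccr7 in 0.797 and 10.9%. Pparg itself was found in 1.74% of PPARg-low cells (1.12 to 2.57%) and in 0 of 2394 PPARg-negative cells, which allows a share of cells with a UMI of up to 0.125% by the limit of 3 counts, or 0.154% by the upper bound of the exact binomial interval. At this depth that limits detection, not the share of cells that express the gene. Foxp3 was found in 2.46 and 2.13% of cells, although both libraries were sorted on the Foxp3 reporter. Without thinning, S1pr1 was found in 12.5 and 28.3%, Ccr7 in 2.78 and 26.4%, Gata3 in 47.8 and 23.4%, Icos in 46.9 and 20.6% and Pparg in 2.53 and 0%. No cluster of another cell type was present in which to measure free RNA, but the B cell gene Cd79a was found in 0.145 and 0.0835% of thinned cells and the myeloid gene Lyz2 in 0.0724 and 0.0835%.

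**Figure D3:**
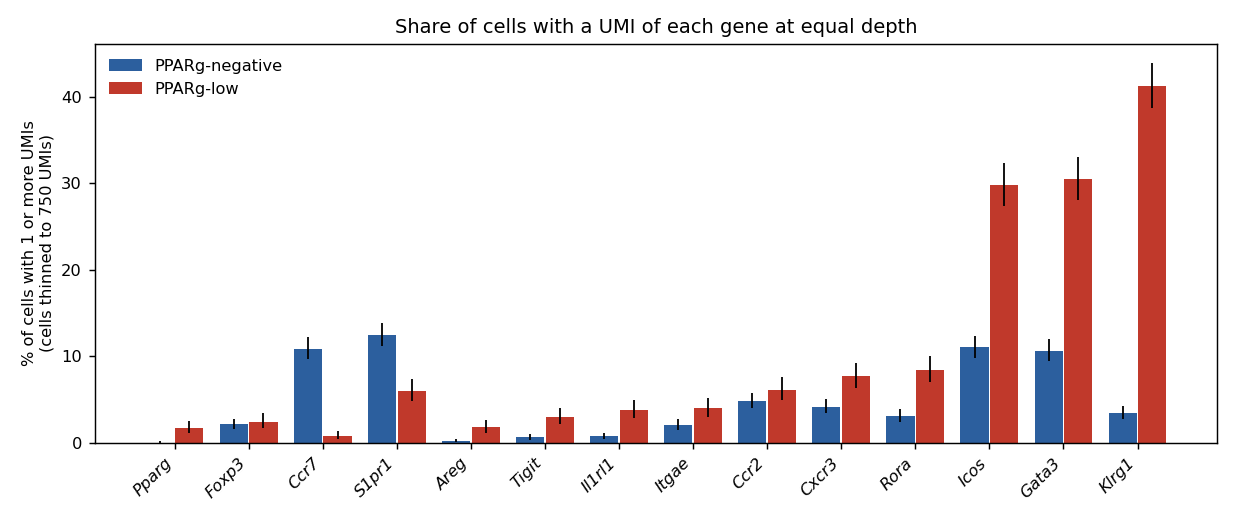
Share of cells (in %) with 1 or more UMIs of each of 14 genes after thinning to 750 UMIs per cell, for 2394 PPARg-negative cells (blue) and 1381 PPARg-low cells (red); bars start at 0 and error bars are exact binomial 95% intervals, which cover counting error only. Klrg1 was found in 41.3% of PPARg-low and 3.43% of PPARg-negative cells, and Ccr7 in 0.797 and 10.9%.

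The differences in the 3 main gene lists were spread over many cells. At 750 UMIs per cell the effector list had a mean of 6.26 UMIs in PPARg-low and 1.24 in PPARg-negative cells, and 8.04 against 49.0% of cells had 0 UMIs of it. The nonlymphoid-tissue list had means of 2.15 and 0.559 UMIs, with 0 UMIs in 25.3 and 68.3% of cells. The resting list had means of 1.12 and 2.65 UMIs, with 0 UMIs in 38.1 and 13.7% of cells. Within ribosome-poor cells the means were 8.94 and 3.57 (effector), 3.01 and 1.52 (nonlymphoid-tissue) and 1.23 and 2.41 (resting), and within ribosome-rich cells 3.34 and 0.752, 1.20 and 0.358, and 1.003 and 2.704. Without thinning the means were 12.8 and 3.10 for the effector list, 4.41 and 1.43 for the nonlymphoid-tissue list, and 2.47 and 7.55 for the resting list.

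Homing and adhesion genes were mixed. The lists are not separate evidence, since 12 of 18 chemokine and egress receptor genes and 11 of 18 nonlymphoid-tissue genes are also on another list. Cxcr6, Itgav and Dgat2, all named below, are nonlymphoid-tissue members too. Of 17 measured chemokine and egress receptors, 8 were higher and 4 lower in the PPARg-low library, with Cxcr6 at 7.07-fold (4.49 to 11.5) and Cxcr3 at 2.01-fold (1.73 to 2.35) beside the gut-homing receptor Ccr9, 8.53-fold lower (3.79 to 23.8, 6 against 104 UMIs). Their median log2 ratio was 0.56 (percentile 96.9 of 10000 random lists matched on expression). Of 12 measured integrins and selectin ligands 9 were higher and 1 was lower (median 0.99, percentile 100), led by Itgb8 at 5.60-fold (4.29 to 7.36) and Itgav at 4.16-fold (3.20 to 5.43). Of 15 measured S100, galectin and annexin genes 10 were higher and 0 lower (median 0.94, percentile 100), with Lgals3 at 5.78-fold (4.45 to 7.59) and S100a4 at 3.15-fold (2.88 to 3.44). Of 5 measured gut Treg genes 3 were higher and 1 lower (median 0.76, percentile 95.5), with Ahr, a receptor for dietary ligands, at 3.35-fold (2.45 to 4.59). Relative to the median of all genes the higher members numbered 7, 7, 8 and 2 in these 4 lists, with as many lower ones as before.

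These homing and adhesion groups depended on the ribosomal share. In ribosome-poor cells the medians were -0.35 for chemokine and egress receptors, -0.30 for integrins, -0.07 for S100, galectin and annexin genes and -0.24 for gut Treg genes, against 0.75, 0.78, 1.06 and 0.46 in ribosome-rich cells. S100a4 was 5.40-fold higher in ribosome-rich cells (4.78 to 6.10) and at 0.729-fold in ribosome-poor cells (0.638 to 0.834). Cxcr3 lay at 2.09-fold (1.62 to 2.69) and 0.707-fold (0.578 to 0.864), and Itgb1 at 3.95-fold (3.31 to 4.72) and 0.788-fold (0.664 to 0.937). Itgae, the integrin chain of tissue-resident T cells, was 2.16-fold higher over all cells (1.68 to 2.77), with 1.70-fold (0.9996 to 2.85) and 0.753-fold (0.561 to 1.01) in the 2 kinds of cells. Itgb8 and Itgav were higher in both, at 5.17-fold and 3.31-fold in ribosome-rich and 2.48-fold and 2.20-fold in ribosome-poor cells. In ribosome-poor cells Cxcr6 was 1.96-fold higher (1.18 to 3.41), Lgals3 lay at 1.40-fold (1.01 to 1.97) and Ccr9 at 1.14-fold (0.243 to 7.02, 6 against 3 UMIs). Ahr was at 2.53-fold (1.53 to 4.15) in ribosome-rich and at 1.52-fold (0.985 to 2.39) in ribosome-poor cells, both under its pooled ratio.

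**Figure D4:**
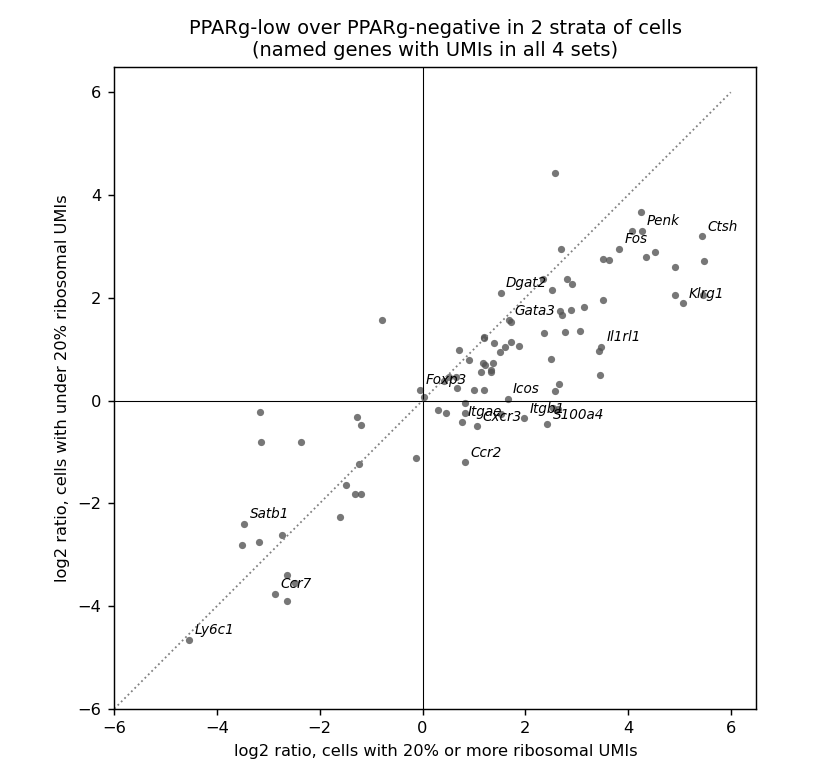
Log2 ratio of CPM in PPARg-low over PPARg-negative cells with a ribosomal share of 20% or more (horizontal axis) and under 20% (vertical axis), for the 94 named genes with UMIs in all 4 sets of cells; the dotted diagonal marks equal ratios. Penk, Klrg1 and Gata3 lie above 0 and Ly6c1, Satb1 and Ccr7 below 0 on both axes, while S100a4, Cxcr3, Itgb1, Itgae and Ccr2 lie above 0 on the horizontal and below 0 on the vertical axis.

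Suppressive mediator genes were higher in the PPARg-low library for 9 of 10 measured members and lower for 0 (median 2.12, percentile 100, 6 members shared with other lists). Ebi3, a subunit of interleukin 35, was 7.46-fold higher (5.71 to 9.86), and the list median was 2.15 in ribosome-rich and 0.78 in ribosome-poor cells. Treg identity genes had 6 of 12 higher and 1, Gpr83, lower (median 0.66, percentile 99.7), with Ctla4 at 3.88-fold (3.59 to 4.20), Tnfrsf18 at 3.19-fold (3.04 to 3.34) and Ikzf2 at 2.68-fold (2.58 to 2.78), and list medians of 0.37 in ribosome-rich and 0.22 in ribosome-poor cells. All 6 measured Th1-like genes were higher (median 1.64, percentile 99.99), with the chemokine gene Ccl5 at 8.96-fold (7.97 to 10.1) and Nkg7 at 7.24-fold (5.94 to 8.88). The Th1-like median was 2.05 in ribosome-rich and -0.04 in ribosome-poor cells, where Ccl5 was still 3.88-fold (2.99 to 5.09) and Nkg7 3.34-fold higher (2.46 to 4.62). Ebi3 was 3.39-fold (2.19 to 5.46), Ctla4 1.92-fold (1.71 to 2.16) and Ikzf2 1.46-fold (1.37 to 1.55) in those cells. Follicular regulatory genes had 3 of 7 higher and 1 lower (median 0.39, percentile 78.6, and 0.41 and 0.38 in ribosome-rich and ribosome-poor cells), with Tox2 at 5.73-fold (3.68 to 9.17), and at 2.52-fold in ribosome-poor cells (1.09 to 6.77). NF-kB targets had 9 of 13 higher and 0 lower (median 0.84, percentile 100), with Icam1 at 2.84-fold (2.44 to 3.31), 1.62-fold in ribosome-poor cells (1.27 to 2.09), and the near-identical paralogs Bcl2a1d and Bcl2a1b at 6.96-fold and 3.38-fold, whose counts may be split between copies. The NF-kB median was 0.73 in ribosome-rich and 0.72 in ribosome-poor cells. Relative to the median of all genes, 5 NF-kB targets and 5 Treg identity genes were higher.

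Among PPARg-linked lipid metabolism genes, 5 of 11 measured members were higher and 0 lower (median 0.64, percentile 97.0), and relative to the median of all genes 3 were higher; the medians were 0.51 in ribosome-rich and 0.25 in ribosome-poor cells. The triglyceride synthesis gene Dgat2 was 4.14-fold higher (2.97 to 5.82), with 2.87-fold in ribosome-rich and 4.29-fold in ribosome-poor cells, and the lipid droplet coat gene Plin2 was 2.36-fold higher (1.83 to 3.04). Cholesterol synthesis genes had 1 of 11 higher and 3 lower (median -0.08, percentile 0.34), with the sterol-regulated genes Idi1 at 2.30-fold lower (1.44 to 3.84) and Sqle at 2.07-fold lower (1.16 to 3.91). Their medians were -0.36 in ribosome-rich and -0.69 in ribosome-poor cells, and relative to the median of all genes 0 were higher and 5 lower. In ribosome-poor cells Idi1 was 3.52-fold lower and Sqle lay at 0.796-fold (0.217 to 3.18). Glycolysis genes had 4 of 13 higher and 0 lower (median 0.38, percentile 85.3), led by Tpi1 at 2.20-fold (1.85 to 2.63), which lay at 1.48-fold in ribosome-poor cells (0.991 to 2.25). The glycolysis medians were 0.32 in ribosome-rich and 0.13 in ribosome-poor cells, and relative to the median of all genes 2 were higher and 1 lower. Interferon response genes had 1 of 15 higher and 3 lower (median -0.03, percentile 0.78), with Ifit3 at 3.16-fold lower (1.94 to 5.43) and Usp18 at 2.98-fold lower (2.21 to 4.09); the medians were 0.02 in ribosome-rich and -0.25 in ribosome-poor cells, and relative to the median of all genes 0 were higher and 3 lower. Cell cycle genes had 11 of 15 higher and 0 lower (median 0.93, percentile 99.99), with Rrm2 at 3.61-fold (2.62 to 5.01), but their median was 1.49 in ribosome-rich and -0.17 in ribosome-poor cells, where Rrm2 lay at 0.902-fold (0.554 to 1.49), and relative to the median of all genes 8 were higher.

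Among markers of other cell types, the B cell gene Cd74 had 1509 UMIs in the PPARg-low and 712 in the PPARg-negative library and the myeloid gene Cst3 777 and 857. The 8 NK and CD8 T cell markers had 104 and 198 UMIs, a summed ratio of 1.07 (0.834 to 1.36), with 0.603 (0.407 to 0.872) in ribosome-rich and 1.63 (1.01 to 2.72) in ribosome-poor cells. The most abundant of them, Cd8b1, lay at 0.578-fold (0.364 to 0.884) and 2.98-fold (1.59 to 6.08) in the same sets. Plasma cell markers had 14 and 8 UMIs and erythroid markers 38 and 11 UMIs, with no member measured, and of 10 myeloid markers only Cst3 was measured, at 1.84-fold (1.67 to 2.03) over all cells and 1.18-fold (0.996 to 1.40) in ribosome-poor cells. Of 7 measured B cell genes 1 was higher, Cd74 at 4.31-fold (3.94 to 4.72, and 2.09-fold in ribosome-poor cells), and 3 were lower, among them Ly6d at 37.4-fold lower (6.51 to 1496, 1 against 76 UMIs), with a median of -1.09 that turned to 0.24 when every cell had equal weight and was -2.37 in ribosome-rich and -0.23 in ribosome-poor cells. Of 4 measured conventional CD4 T cell genes 2 were lower, Igfbp4 and Tnfsf8, the latter 2.83-fold (1.94 to 4.26), and Il2 lay at 1.06-fold (0.763 to 1.46). Ribosomal protein genes made up 22.2% of PPARg-low and 35.5% of PPARg-negative UMIs, and the 13 mitochondrially encoded genes 4.09 and 2.78%. Immediate early and heat shock genes had 10 of 14 higher and 0 lower (median 1.37, percentile 100), with Hspa1a at 19.3-fold (10.6 to 38.5) and Fos at 15-fold (9.99 to 23.3), while Hspa8 lay at 1.04-fold. Their medians were 1.33 in ribosome-rich and 1.42 in ribosome-poor cells, and in the latter Hspa1a was 9.80-fold and Fos 7.74-fold higher.

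Joint clustering of the kept cells gave 10 clusters, of which clusters 4, 5 and 7 held 50 or more cells of each library. Within these, the nonlymphoid-tissue list had medians of 0.89, 0.34 and 0.58 over 11, 5 and 12 measured members. The effector list had medians of 0.74, 0.86 and 0.40 over 13, 13 and 15 members. All were smaller than over all cells, though they rest on fewer members. The resting list had -0.73, -0.27 and 0.28 over 11, 9 and 7 members. Members of these lists were not kept out of the clustering, which can by itself make differences inside clusters smaller. Klrg1 was 3.78-fold higher in the PPARg-low cells of cluster 4 (3.19 to 4.49) and 7.97-fold in those of cluster 5 (4.19 to 17.0). In cluster 7 Klrg1 was 1.90-fold higher (1.41 to 2.64). Gata3 was higher in all 3, at 1.87-fold (1.47 to 2.38), 3.35-fold (2.21 to 5.26) and 2.19-fold (1.43 to 3.52). Cluster 7 drew 668 of its 721 cells from the PPARg-low library, so values within it rest on 53 PPARg-negative cells.

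Of 36 pairs computed, only some are given here. In both libraries, each pair of Ccr2, Itgae and Il1rl1 was found in the same cells more often than their single shares would give. The intervals below take the product of the single shares as fixed, so they leave out the counting error of those shares. At 750 UMIs, 20 of 1381 PPARg-low cells had UMIs of both Ccr2 and Itgae against 3.39 from the product of the shares, a ratio of 5.91 (3.62 to 9.09). Il1rl1 and Itgae gave 5.21 (2.61 to 9.30) and Il1rl1 and Ccr2 3.07 (1.47 to 5.62). In the PPARg-negative library the 3 pairs gave 5.52 (2.94 to 9.43), 13.6 (4.41 to 31.6) and 10.4 (4.76 to 19.7). Within ribosome-poor cells they gave 4.02 (2.43 to 6.23), 3.41 (1.64 to 6.24) and 2.31 (1.11 to 4.22) in the PPARg-low library, and 1.62 (0.844 to 2.81), 4.06 (1.32 to 9.40) and 2.76 (1.27 to 5.19) in the PPARg-negative library. Among PPARg-low ribosome-rich cells only 1, 1 and 0 cells held both genes of these 3 pairs. Klrg1 was found with Cxcr3 at 1.05 times the product in the PPARg-low (0.773 to 1.39) and 5.26 times in the PPARg-negative library (3.12 to 8.29). In the latter, ribosome-poor cells alone gave 1.49 (0.818 to 2.46) and ribosome-rich cells alone 10.3 (2.80 to 26.3), the last from 4 cells with both. In PPARg-low cells Klrg1 and Gata3 were found together at 1.23 times the product over all cells (1.08 to 1.39), but at 1.28 times (0.984 to 1.62) within ribosome-rich and 1.13 times (0.977 to 1.30) within ribosome-poor cells, where both intervals include 1; the PPARg-negative library gave 1.72 (0.962 to 2.83). In the PPARg-negative library Klrg1 was found with Il1rl1 at 11.4 times (4.57 to 23.4) and with Itgae at 8.94 times the product (5.01 to 14.7), against 3.22 (1.30 to 6.58) and 2.23 times (1.12 to 3.95) within its ribosome-poor cells. Its ribosome-rich cells held 0 cells with Klrg1 and Il1rl1, and 4 with Klrg1 and Itgae, at 24 times the product (6.54 to 61.4). The same pairs gave 1.42 (0.966 to 2.002) and 1.23 (0.822 to 1.77) in the PPARg-low library.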

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

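The alternatives built on the ribosomal share, on ratios relative to the median of all genes, and on the stricter filter (1000 genes, under 5% mitochondrial UMIs) for genes and shares were chosen after seeing the data. No paired analysis was possible because each group holds 1 library. Apart from medians within clusters, which are given below, the resting, effector and nonlymphoid-tissue list medians kept their direction under every alternative run. Scaling by a trimmed mean (TMM) factor shifted the median of all genes by -0.32 and a total without ribosomal and mitochondrial genes by -0.26 on the log2 scale. The resting median was then -2.31 and -2.24, the effector median 2.05 and 2.12, and the nonlymphoid-tissue median 1.99 and 2.06; relative to the median of all genes the 3 values were -2.27, 2.09 and 2.03. The stricter cell filter gave 2.14 for the effector and 2.09 for the nonlymphoid-tissue list, and equal weight per cell gave 2.27 for the effector list. Cells with under 20% ribosomal UMIs gave -1.61 (resting), 1.43 (effector) and 1.14 (nonlymphoid-tissue), and the other cells gave 2.27 (effector).

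In cells with under 20% ribosomal UMIs, list medians took the opposite sign for chemokine and egress receptors (-0.35), gut Treg (-0.24), integrins (-0.30), S100, galectin and annexin (-0.069), Th1-like (-0.042), cell cycle (-0.17) and mitochondrially encoded genes (-0.02). There the log2 ratios also reversed for Ccna2 (-0.17), Ccr2 (-1.20), Ccr9 (0.18), Cxcr3 (-0.50), Il18r1 (-0.27), Itgae (-0.41), Itgb1 (-0.34), Itgb7 (-0.24), Oas1a (-0.25), Pgam1 (-0.052), Rrm2 (-0.15) and S100a4 (-0.46), and the share differences for Ccr2 (-11.9 percentage points), Itgae (-1.56) and Cxcr3 (-5.02); the cause was not tested. The B cell list median turned to 0.24 with equal weight per cell, to 0.35 with thinned cells and to 1.30 for members with 100 or more UMIs, and Cd79a to 0.24 and 0.21 under the former 2; 25 of its UMIs lay in 4 PPARg-negative cells.

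Foxp3 had a log2 ratio of -0.051 in cells with 20% or more ribosomal UMIs. The Pparg ratio against the floor of 3 counts, 4.86 on the log2 scale, was 3.85 with the stricter filter, 3.85 with thinned cells and 1.99 in cells with under 20% ribosomal UMIs, since fewer UMIs raise the floor. The Klrg1 share difference of 37.8 percentage points was 50.2 without thinning, 30.1 at 500 UMIs, 27.2 and 38.6 in cells with 20% or more and under 20% ribosomal UMIs, and 30.5 with the stricter filter. Mean UMIs per cell differed by -5.07 (resting), 9.66 (effector) and 2.98 (nonlymphoid-tissue) without thinning, and by -1.03, 3.49 and 0.994 at 500 UMIs, as fewer UMIs per cell require. The within-cluster median nearest to or past 0 was -0.34 and -0.17 (resting) and 0.52 and 0.27 (effector) at resolutions 0.5 and 1.5, -0.10 (nonlymphoid-tissue) at 1.5, and 0.25 (effector) and 0.15 (nonlymphoid-tissue) with 30 components; the cause was not tested. Over all named genes and alternatives, 743 single-gene values stayed within their counting interval, 7 of them, for Il2, Cd8b1 and Cd40lg, with the opposite sign, and 273 lay outside it, 269 with the same sign. The other 4 were Ccr2 and Foxp3 as above and Cd8b1 at -0.12 with the stricter filter and -0.79 in cells with 20% or more ribosomal UMIs. A further 13 values were counted apart as reversed, all with the opposite sign. Of these, 11 came from cells with under 20% ribosomal UMIs, 1 from equal weight per cell and 1 from thinned cells. Depth limits genes with few UMIs, such as Pparg with 43 and Foxp3 with 100 and 146.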

Other observations

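The tests of the resting and nonlymphoid-tissue difference against the ribosomal share, and against NK or CD8 T cells within ribosome-poor cells, were chosen only after their results were seen, and the other tests below were set out before theirs. Differences inside clusters varied by cluster. In cluster 4 the PPARg-low cells had 33 UMIs of Dgat2, a triglyceride synthesis gene, against 1 in the PPARg-negative cells (53.5-fold, 8.95 to 2176), but in cluster 7 Dgat2 lay at 1.14-fold (0.365 to 5.75, 43 against 3 UMIs). Cxcr6, a receptor for tissue retention, was 4.01-fold higher in cluster 4 (2.31 to 7.23). Cxcr3 lay at 1.01-fold in cluster 4 (0.807 to 1.27), at 0.361-fold (0.198 to 0.644) in cluster 5 and at 0.502-fold (0.278 to 0.984) in cluster 7. The PPARg-low cells of cluster 7 had less Icos, at 0.614-fold (0.479 to 0.797), against 1.08-fold (0.940 to 1.25) in cluster 4 and 0.862-fold (0.674 to 1.10) in cluster 5.

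Ribosome-poor cells also had more effector gene UMIs inside the PPARg-negative library. Ribosomal protein genes held 13.4% of UMIs in its ribosome-poor and 38.3% in its ribosome-rich cells, which leaves the former more of the thinned total for other genes. That room is too small to give the whole difference. At 750 UMIs the means were 3.57 effector list UMIs per ribosome-poor cell and 0.752 per ribosome-rich cell of that library, and Klrg1 was found in 14.5 and 1.11% of them. Ccr2 was found in 21.7% of PPARg-negative ribosome-poor cells (17.9 to 26.0%), against 9.85% of PPARg-low ribosome-poor cells (7.77 to 12.3%).

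The lower resting genes and higher nonlymphoid-tissue genes of the PPARg-low library were weighed against its larger part of ribosome-poor cells. That mix may account for part of the size, but a mix of 2 kinds of cells split at 20% does not account for the whole. The nonlymphoid-tissue list median still exceeded that of all genes by 1.12 on the log2 scale (0.857 to 1.60) in ribosome-poor cells and by 2.30 in ribosome-rich cells. The share itself still differed inside both kinds. Its medians were 10.2% in PPARg-low against 12.5% in PPARg-negative ribosome-poor cells, and 27.9 against 37.9% in ribosome-rich cells. The split therefore cannot exclude the ribosomal share as the whole cause. For the pooled difference, NK or CD8 T cells, which also express Klrg1, were weighed by 8 markers. The summed ratio of 1.07 (0.834 to 1.36) argued against such cells as far as these markers reach. The most abundant of them, Cd8b1, had 30.7 and 24.9 CPM. It gave 89 of the 104 PPARg-low and 147 of the 198 PPARg-negative UMIs of the sum, which therefore says little about NK cells. Both libraries were sorted on the Foxp3 reporter, but how far the sort removed such cells was not tested. Within ribosome-poor cells the summed ratio was 1.63 (1.01 to 2.72), which leaves a part from such cells open there. Cd8b1 gave 63 of 69 PPARg-low and 12 of 24 PPARg-negative UMIs of that sum. Another of the markers, Cd8a, was found in 0% of thinned PPARg-low (0 to 0.510%) and 0.483% of thinned PPARg-negative ribosome-poor cells (0.0586 to 1.73%). The list median there was 1.14 with and 1.14 without the cells that held any of these markers. Only 58 of 951 PPARg-low and 17 of 614 PPARg-negative ribosome-poor cells held one. At their depth markers can be missed, so this comparison cannot decide. Over all kept cells the list median was 2.31 with and 2.64 without the cells that held a marker. What also stays open is the PPARg reporter sort that the design names, and any difference in mice, handling or capture between 2 unreplicated libraries, which was not tested.

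Immediate early and heat shock genes, with Fos 15-fold and Hspa1a 19.3-fold higher in the PPARg-low library, could come from cell handling. The mix of ribosome-poor cells was argued against as the whole cause, because the list median exceeded that of all genes by at least 1.09 (0.671 to 1.22) in both kinds of cells. The ribosomal share still differed between the libraries inside both kinds, so the split cannot exclude that share as the cause. Handling that raised these genes in every cell of the PPARg-low sort should show in resting Treg-like cells too; there the list median exceeded that of all genes by 0.089 (-0.156 to 0.736) over 10 members. With 40 PPARg-low cells against 1147 in those clusters the interval includes 0.5, so handling and activation cannot be told apart for these genes.

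Ighm, the immunoglobulin heavy chain gene of B cells, had 1195 CPM in the PPARg-low library and 604 CPM in the PPARg-negative library, and was found in 62.8% of the 4248 kept cells with under 5 B cell marker UMIs. Free RNA from B cells was argued against: those cells had 0.0247 Igkc UMIs per Ighm UMI (0.0211 to 0.0287), against 1.24 (0.709 to 2.19) in the 4 cells with 5 or more. An Ighm transcript made by the Tregs themselves may be the source, as a hypothesis that 3′ counts without transcript structure leave open. Within ribosome-poor cells the Ighm ratio between libraries was 1.07, and within ribosome-rich cells it was 2.33.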
